A study of Mus musculus with 6 samples.

How the data were processed

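Gene expression was measured in caudal arteries, the main artery of the tail, of 4-week-old (P28) mice that either carried Notch3 (Notch3+/+) or lacked it (Notch3-/-). Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns and checked for quality, and biotinylated cRNA was made from 2.5 µg of it with a one-cycle labelling assay. Per the series' design text, each RNA came from arteries pooled over several mice and was hybridised to a MOE430 2.0 Affymetrix chip, on which a set of short probes reports each transcript. The pools held 4, 3 and 3 mice in Notch3+/+ replicates 1 to 3 and 4 mice in each Notch3-/- replicate. The labels call the 3 pools of each genotype biological replicates, and each pool counts here as 1 sample.

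The deposited values are log2 expression values per probe set, made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes arrays to shared quantiles and summarises the probes of a set. Its version, implementation and chip definition are not given in the sources used here. The log2 scale was read from the values, which ran from 1.38 to 13.38 with 2 decimals and had array medians between 4.50 and 4.57. No scanner files were used here, so background and scanning could not be examined, and the values carry no detection call. RMA compresses differences of dim and of nearly saturated probe sets, so a fold change there can be understated. No batch, scan day or slide is given in the labels.

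The file held 45101 probe sets, of which 64 were chip controls and were left out of all tests. Names came from the platform annotation paired with the probe sets. It gave 34945 of the remaining probe sets 1 gene symbol, 932 several genes and 9160 none, and no gene was named from a probe set with several. Of the probe sets with 1 symbol, 34741 were matched by gene number to the RefSeq table of mouse assembly GRCm38.p6, which updated symbols and was used only for names and neighbourhood on the chromosome. Probe sets whose mean over the 6 arrays lay below the 40th percentile (3.83 on the log2 scale) were left out, which left 27027.

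Differences between genotypes were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the log2 values with genotype as the only term. The two-sided p-values were adjusted by the Benjamini-Hochberg method over the 27027 probe sets, with a threshold of 0.05. Every adjusted p for a gene comes from this fit unless another test is named, and changes are Notch3-/- minus Notch3+/+ in log2 units. Folds are the antilog of these changes. For statements about genes, each gene was represented by the probe set with its highest mean, which gave 18193 genes, 12732 of them tested. Among the genes named, tested probe sets of Adam10, Pdgfrb, Ppp1r12b, Arhgef12, Sox17, Nr2f2, Flt4, Laptm5, Klf6, Atp5a1, Acta2, Rad21, Uty and Xist differed in sign. Differences in size between probe sets of 1 sign are given for some genes only. The number of arrays, 3 per genotype, limits the precision of every value.

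Before the data were examined, 29 gene lists were fixed: Notch components and targets, contractile, ion channel, receptor, RhoA, adhesion and matrix genes, several cellular programmes, and markers of cell types that a dissected tail artery can hold. Of these, 27 were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists tested. The sex-linked list was reported without a list test, and the erythroid list had too few members above the level filter (under 3). Camera with a correlation estimated for each list and limma's fry were run beside it. List members were also adjusted over the list alone. Called genes within 20 Mb of Notch3 were compared with all others by a one-sided Fisher's exact test. The naming rule, fixed at the same time, took Notch3 and Grip2, the 15 largest falls and 15 largest rises among called genes, and up to 4 members per list with the smallest unadjusted p. Genes outside it were chosen after their values were seen and are named as such or as completing a count. No source was recorded for placing Nrip2 among the Notch targets or Grip2 among the adhesion genes. Their changes therefore do not test those categories.

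The settings varied were the level filter, the variance model, a further quantile normalization, centring on the median, array weights, weights by mice pooled, the replicate number as a block, the probe sets representing a gene, the threshold, the chromosome window, the list test and the omission of each array. The fit and the list test were tested on simulated arrays with the means and spreads of the 27027 probe sets, with 200 of them changed. Of changes of 1.5-fold, 52% were called, of 2-fold 72%, of 4-fold 98% and of 8-fold 100%. No call had the wrong sign, and 10 calls were made among probe sets that had not been changed. All 3 shifted lists were called, as was 1 of 24 lists left unshifted. The simulated probe sets varied independently of one another, whereas correlations estimated in the real lists reached 0.907, for mast cell markers. The planted shift also exceeded the median change of every real list but the mast cell markers. The simulation therefore does not show how often lists of correlated genes are called without a shift. Figures were drawn with matplotlib 3.10.9.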

Results

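Expression of 27027 probe sets was compared between 3 pools of caudal arteries from Notch3-/- mice and 3 pools from Notch3+/+ mice at 4 weeks of age. Notch3 is a Notch receptor of arterial smooth muscle cells, and the comparison asks which transcripts differ in an artery that lacks it. The 6 arrays correlated with one another at r between 0.990 and 0.996 across probe sets, which are not independent replicates. The first principal component held 45.2% of the variance and set Notch3-/- replicate 2 apart, at 39.5 against -17.1 to 5.85 for the other arrays.

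Notch3 itself was lower in all 3 Notch3-/- pools. The brighter of its 2 probe sets read 9.99 ± 0.08 (SD, n = 3) in Notch3+/+ and 6.27 ± 0.35 (SD, n = 3) in Notch3-/- arteries. It fell by 3.72 on the log2 scale (SE 0.17), or 13.2-fold, with an adjusted p of 0.000529 from limma. The other probe set fell by 3.92, or 15.1-fold, with an adjusted p of 6.19e-05. Every Notch3-/- pool, at 5.87 to 6.51 on the brighter probe set, lay below every Notch3+/+ pool, at 9.94 to 10.09, so the genotype labels match this transcript. The labels do not describe the targeted allele, so whether either probe set lies inside a deleted part is unknown here.

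Besides Notch3, the largest falls were those of Perp, Pln, Tbx2 and Rcan2, each over 3-fold. Perp, a membrane protein of desmosomes, fell by 2.12 (SE 0.14), or 4.35-fold, from 6.90 ± 0.25 to 4.78 ± 0.14 (SD, n = 3). Pln, which encodes phospholamban, an inhibitor of the sarcoplasmic reticulum calcium pump, fell by 2.05 (SE 0.22), or 4.15-fold, and its 3 probe sets changed by -2.05 to -1.91, though 1 of them passed. Tbx2, a T-box transcriptional repressor, fell by 1.78 (SE 0.10), or 3.43-fold, and Rcan2, a regulator of calcineurin, fell by 1.73 (SE 0.11), or 3.31-fold. Susd5 fell by 1.67 (3.19-fold) and the metalloproteinase inhibitor gene Timp4 fell by 1.35 (2.54-fold). Grip2, a PDZ scaffold protein, fell by 1.24 (SE 0.09), from 7.14 ± 0.11 to 5.90 ± 0.11 (SD, n = 3), with an adjusted p of 0.0038. Kcna5, the voltage-gated potassium channel Kv1.5, also fell by 1.24 (2.36-fold, adjusted p = 0.00534). The dopamine receptor gene Drd1 (-1.07), the muscle phosphoglycerate mutase gene Pgam2 (-1.02), Guca1a (-1.01), the haptoglobin gene Hp (-0.99), the cytoskeletal adaptor gene Sorbs2 (-0.91) and the cadherin gene Cdh6 (-0.90) completed the 15 largest falls. The 3 probe sets of Sorbs2 disagreed, with changes from -0.94 to -0.04.

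The largest rise was that of Npy6r, a receptor of the neuropeptide Y family, followed by Des, C1qtnf3 and Casq2. Npy6r rose by 2.54 (SE 0.13), or 5.82-fold, from 3.73 ± 0.10 to 6.27 ± 0.26 (SD, n = 3), with an adjusted p of 0.000958. Its Notch3+/+ level, like that of Coch, lay below the filter level of 3.83. The other Npy6r probe set rose by 1.48 (2.80-fold), less than the rises of Des, C1qtnf3 and Casq2. Des, which encodes the intermediate filament protein desmin, rose by 2.01 (SE 0.15), or 4.03-fold, from 6.41 ± 0.10 to 8.42 ± 0.29 (SD, n = 3). Casq2, the calcium-binding protein calsequestrin 2 of the sarcoplasmic reticulum, rose by 1.62 (SE 0.09), or 3.07-fold. C1qtnf3, which encodes a secreted protein, rose by 1.92 (3.78-fold), the extracellular matrix protein gene Frem2 by 1.61 (3.05-fold), the matricellular gene Ccn5 by 1.60 (3.03-fold), the microfibril-associated gene Ltbp2 by 1.57 (2.96-fold) and the growth factor binding protein gene Igfbp2 by 1.36 (2.56-fold). The retinol carrier gene Rbp4 rose by 1.25, the chloride intracellular channel gene Clic5 by 1.16, the tenascin C gene Tnc by 1.13 and the adenosine deaminase gene Ada by 1.09. Coch (0.98), the contactin gene Cntn6 (0.94) and the proteoglycan gene Epyc (0.87) were the remaining genes of the 15 largest rises.

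**Figure D1:**
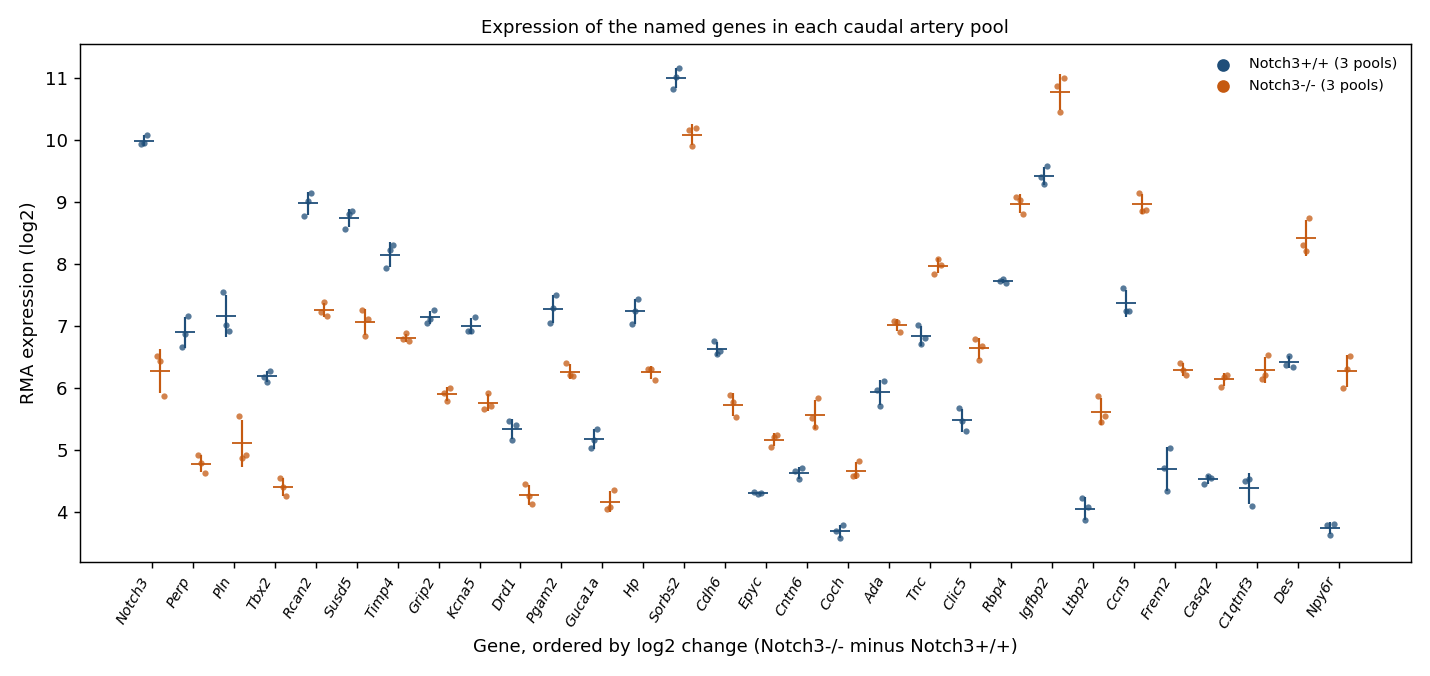
Expression (RMA log2, vertical axis) of the genes with the largest falls and rises (horizontal axis, ordered by change) in each caudal artery pool, Notch3+/+ in blue and Notch3-/- in orange. Points are the 3 pools, horizontal marks the mean and vertical bars the SD; the mean of Notch3 goes from 9.99 to 6.27 and that of Npy6r from 3.73 to 6.27.

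In all, 68 of the 27027 probe sets passed the threshold, 37 of them higher and 31 lower in Notch3-/- arteries. At 1 probe set per gene, 41 of 12732 genes passed, 25 higher and 16 lower, and 24 of these changed at least 2-fold, 12 in each direction. An unadjusted p under 0.05 was found for 3070 probe sets. The count of called probe sets was 13 without Notch3+/+ replicate 2, 17 without Notch3-/- replicate 3, 23 without Notch3+/+ replicate 3 and 37 without Notch3-/- replicate 2. In all 41 genes the pools of the genotypes did not overlap, so leaving out 1 array could not reverse a direction. Notch3, Rcan2, Des, Perp, C1qtnf3, Casq2, Tbx2 and Npy6r were called whichever array was left out, and 33 genes were not. Without Notch3+/+ replicate 2, for example, the adjusted p of Grip2 was 0.0506, of Kcna5 0.0565 and of Pln 0.128.

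Among Notch pathway genes, Notch3 fell, and Nrip2, placed in the fixed list of targets, fell on all 3 of its probe sets, 2 of which passed. Of 25 Notch receptors, ligands and signalling components tested, 1 fell (Notch3) and 0 rose, both over all genes and adjusted over the list alone. Notch1 (-0.20), the ligand gene Jag1 (-0.18) and the receptor-processing protease gene Adam10 (0.17) had adjusted p of 0.437 or more. Of 11 Notch target genes, 0 passed over all genes in limma by their brightest probe set, and 3 had an unadjusted p under 0.05. Nrip2, a nuclear receptor interacting protein gene, passed on its other 2 probe sets, which fell by 1.10 (adjusted p = 0.0204) and 1.22 (adjusted p = 0.0499). On its brightest probe set Nrip2 fell by 1.07 (SE 0.17), which passed adjusted over the list alone. Also adjusted over the list alone, Pdgfrb, the PDGF receptor beta gene, rose by 0.42 (SE 0.08), although the second Pdgfrb probe set read -0.09. Hey1 (0.22) and the feedback inhibitor gene Nrarp (-0.37) did not pass, nor did Heyl (0.02), Hes1 (-0.22) and Hey2 (0.15), which were chosen after their values were seen. Neither list shifted as a whole, with medians of 0.02 and 0.02 and camera adjusted p of 0.807 and 0.900. In both lists the mean was below 0 and camera's direction was down although the median was above 0.

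Contractile genes moved in both directions. Of 24 smooth muscle contractile genes, Des and Casq2 rose and Pln fell over all genes. Adjusted over the list alone, 4 rose and 3 fell: the actin gene Actg2 (0.66) and the calponin gene Cnn1 (0.51) joined the rises, and the transcriptional coactivator gene Myocd (-0.39) and the smoothelin gene Smtn (-0.58) joined the falls. Acta2 (0.05), Tagln (-0.06) and Myh11 (0.04), the classical markers of differentiated smooth muscle, chosen after their values were seen, did not pass. They read above 12 on a scale that ended at 13.38, where differences are compressed. The list median was 0.04 (camera adjusted p = 0.509). Without Notch3+/+ replicate 3 the list passed, with an adjusted p of 0.0321.

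Arterial ion channel and calcium handling genes were lower as a group with camera, with a median of -0.11 over 28 genes and 20 of them negative (camera adjusted p = 0.0166, and adjusted p = 0.757 with an estimated correlation). The list medians per pool overlapped, at -0.07 to 0.05 in Notch3+/+ and -0.09 to -0.06 in Notch3-/- pools. Kcna5 fell over all genes and 0 rose. Adjusted over the list alone, Kcna5 and the calcium channel subunit gene Cacnb2 (-0.61) fell, and the ryanodine receptor gene Ryr3 (0.52) and the potassium channel subunit gene Abcc9 (0.44) rose. Of 26 genes for vasoactive receptors and cyclic nucleotide signalling, 0 passed over all genes in limma by their brightest probe set, and 8 had an unadjusted p under 0.05. Ptgfr passed on another probe set, which rose by 0.73 (adjusted p = 0.0153). Adjusted over the list alone, the prostaglandin F receptor gene Ptgfr (0.87), the nucleotide receptor gene P2ry6 (0.53) and the angiotensin receptor gene Agtr1a (0.50) rose, and the vasopressin receptor gene Avpr1a (-0.37) and Rgs4 (-0.32) fell. That list had a median of -0.09 and an adjusted p of 0.588. Of 18 RhoA and myosin phosphatase genes, 0 passed in limma over all genes or adjusted over the list alone and 1 had an unadjusted p under 0.05, with values of -0.41 for Arhgef2, -0.35 for Ppp1r12b, 0.21 for Ppp1r14a and -0.21 for Arhgef12, a median of -0.03 and a camera adjusted p of 0.328.

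Adhesion and mechanosensing genes also moved both ways. Of 33 tested, Grip2, a PDZ scaffold gene placed in the fixed list, fell and Fhl2, a LIM domain protein gene, rose by 0.63 over all genes. Adjusted over the list alone, 4 rose and 3 fell: Ankrd1, a stretch-responsive ankyrin repeat protein gene, rose by 1.76 (SE 0.25) and passed over all genes on its other probe set (1.88, adjusted p = 0.041), Csrp2 by 0.42 and the integrin gene Itga1 by 0.48, while Xirp1 fell by 0.84 and the integrin gene Itga7 by 0.40. The list median was 0.00 and its camera adjusted p was 0.973.

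Matrix genes were slightly higher as a group with camera. Their list medians per pool overlapped, at -0.02 to 0.03 in Notch3+/+ and 0.01 to 0.11 in Notch3-/- pools. Of 34 extracellular matrix genes, 22 were positive, with a median of 0.06 (camera adjusted p = 0.0442, and adjusted p = 0.757 with an estimated correlation). Tnc rose over all genes, and Tnc, the proteoglycan gene Vcan (0.65), the periostin gene Postn (0.49) and the collagen crosslinking enzyme gene Loxl1 (0.41) rose adjusted over the list alone. The group call was lost without Notch3-/- replicate 1 (adjusted p = 0.493), without Notch3-/- replicate 3 (0.124), without Notch3+/+ replicate 1 (0.0953) and without Notch3+/+ replicate 3 (0.0548). Fibroblast markers, 4 of which belong to the matrix list, were higher in the same pools, with a median of 0.15. Of 15 basement membrane genes, 0 passed in limma over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. Lama5 read -0.55, Agrn -0.42, Col18a1 -0.35 and Nid1 0.19, and the list median was -0.02 (camera adjusted p = 0.370).

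**Figure D2:**
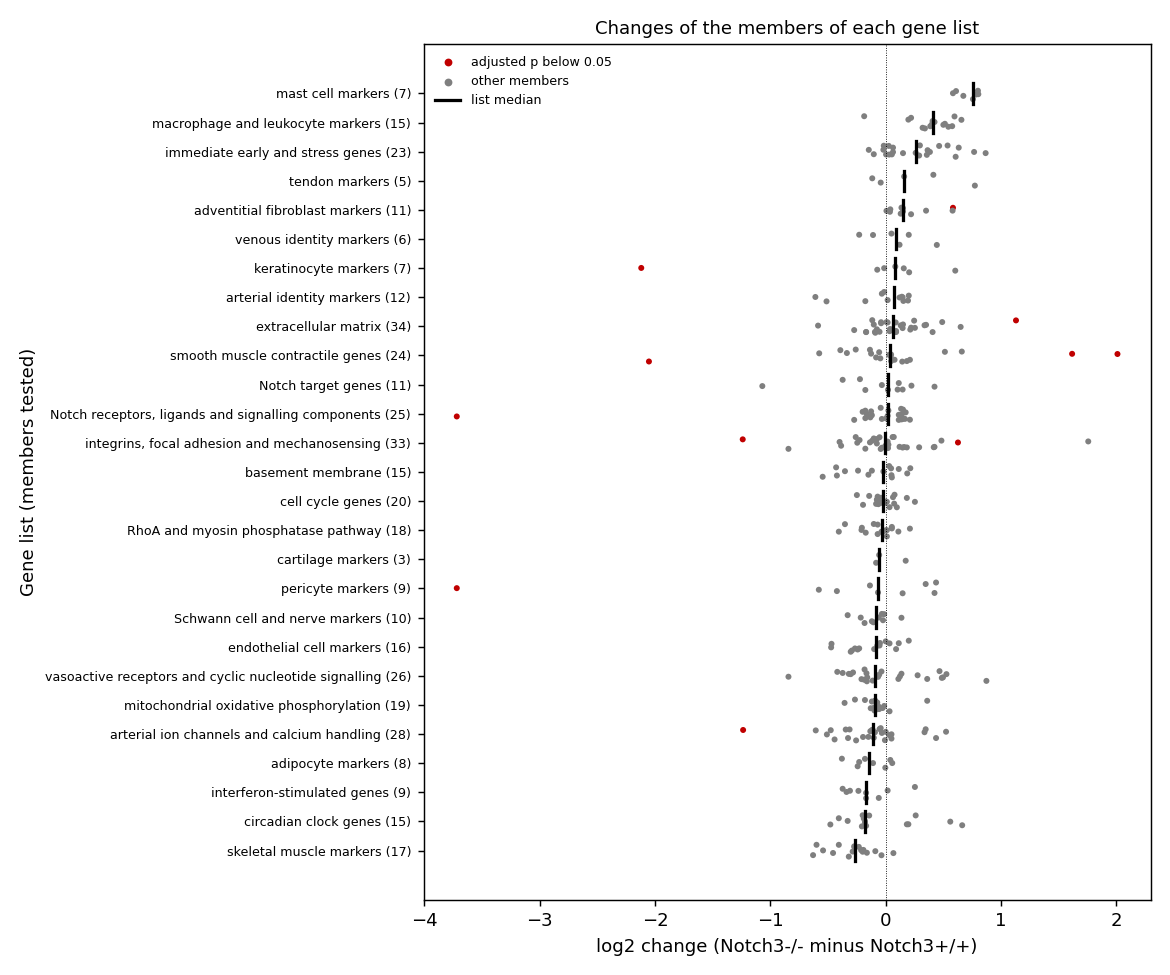
Log2 change between Notch3-/- and Notch3+/+ arteries (horizontal axis) of each tested member of the 27 gene lists (vertical axis, ordered by median, with the number of members tested). Points are genes, red where the adjusted p over all probe sets was below 0.05, and black bars are list medians, which run from -0.27 for skeletal muscle markers to 0.76 for mast cell markers.

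Markers of other cell types differed between the genotypes, and those of mast cells were shifted most. All 7 mast cell markers were higher in Notch3-/- arteries, by 0.58 to 0.80, with a median of 0.76 (camera adjusted p = 0.000184, and adjusted p = 0.757 with an estimated correlation). Over all genes 0 passed in limma. The 4 with an unadjusted p under 0.05 rose adjusted over the list alone: the high-affinity IgE receptor genes Ms4a2 (0.76) and Fcer1a (0.78), the stem cell factor receptor gene Kit (0.61) and the carboxypeptidase gene Cpa3 (0.80). Of 15 macrophage and leukocyte markers, 14 were higher, with a median of 0.41 (camera adjusted p = 0.000184, and adjusted p = 0.757 with an estimated correlation). C1qb, a complement gene, passed on another probe set, which rose by 1.07 (adjusted p = 0.0227). By their brightest probe set 0 passed in limma over all genes or adjusted over the list alone and 6 had an unadjusted p under 0.05, with values of 0.66 for Laptm5, 0.58 for Cd163, 0.50 for Adgre1 and 0.42 for Cd14. All 11 adventitial fibroblast markers were positive, with a median of 0.15 (camera adjusted p = 0.00181, and adjusted p = 0.757 with an estimated correlation). Dpt, which encodes dermatopontin, rose by 0.58 over all genes (adjusted p = 0.0499) and was the gene that passed adjusted over the list alone, beside values of 0.22 for Cd34, 0.58 for Pi16 and 0.35 for Mfap5. Its call was lost whichever array was left out, with adjusted p from 0.0684 without Notch3-/- replicate 1 to 0.261 without Notch3-/- replicate 3. The mast cell list medians per pool overlapped, at -0.50 to 0.65 in Notch3+/+ and 0.52 to 1.04 in Notch3-/- pools.

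Endothelial, adipocyte and skeletal muscle markers were lower as groups with camera, but their list medians per pool overlapped between genotypes. The endothelial medians ran from -0.05 to 0.07 in Notch3+/+ and from -0.14 to -0.025 in Notch3-/- pools. The adipocyte medians ran from -0.09 to 0.04 in Notch3+/+ and from -0.27 to -0.035 in Notch3-/- pools. Of 16 endothelial markers 11 were negative, and the median was -0.09 (camera adjusted p = 0.0344, and adjusted p = 0.757 with an estimated correlation). In limma 0 passed over all genes or adjusted over the list alone and 4 had an unadjusted p under 0.05, with values of -0.47 for the nitric oxide synthase gene Nos3, -0.47 for Pecam1, -0.27 for Egfl7 and -0.23 for Esam. The 8 adipocyte markers had a median of -0.14 (camera adjusted p = 0.049, and adjusted p = 0.757 with an estimated correlation), and the lipid droplet gene Plin4 (-0.38) fell adjusted over the list alone, with 0 passing over all genes and 2 at an unadjusted p under 0.05, beside values of -0.24 for Pnpla2, -0.23 for Cidea and -0.18 for Lipe. The 17 skeletal muscle markers had a median of -0.27 (camera adjusted p = 0.0105, and adjusted p = 0.757 with an estimated correlation), with 0 passing in limma over all genes or adjusted over the list alone, 3 at an unadjusted p under 0.05, and values of -0.63 for Pvalb, -0.60 for Tcap, -0.54 for Pygm and -0.41 for Eno3. Per pool, the skeletal list median ran from -0.71 in Notch3-/- replicate 2 to 0.33 in Notch3-/- replicate 3, against -0.19 to 0.08 in the Notch3+/+ pools. Without Notch3-/- replicate 2 its adjusted p was 0.575. The endothelial call was lost without Notch3+/+ replicate 1 (0.118), Notch3-/- replicate 3 (0.101), Notch3-/- replicate 2 (0.0593) or Notch3+/+ replicate 3 (0.0575). The adipocyte call was lost without Notch3-/- replicate 3 (0.428), Notch3+/+ replicate 1 (0.162), Notch3-/- replicate 1 (0.0987) or Notch3+/+ replicate 2 (0.0734), and the skeletal call also without Notch3-/- replicate 1 (0.0987) or Notch3+/+ replicate 1 (0.0648).

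**Figure D3:**
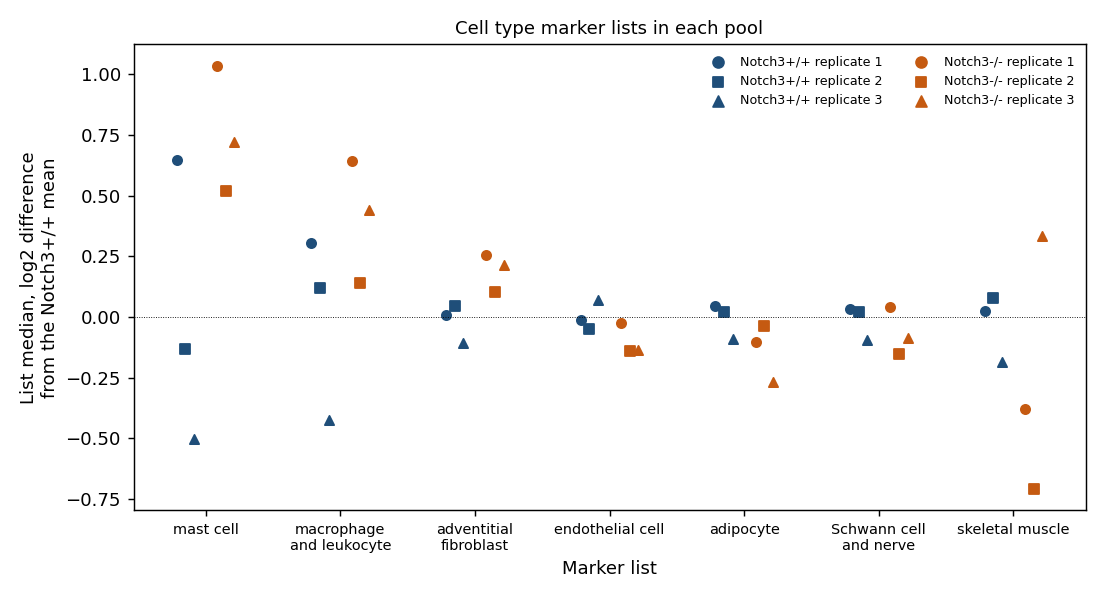
Median of each cell type marker list in each pool (vertical axis, log2 difference from the Notch3+/+ mean) for 7 lists (horizontal axis), Notch3+/+ in blue and Notch3-/- in orange, with circles, squares and triangles for replicates 1, 2 and 3. Mast cell medians run from -0.50 to 0.65 in Notch3+/+ and from 0.52 to 1.04 in Notch3-/- pools, and skeletal muscle medians spread from -0.71 to 0.33 among the Notch3-/- pools.

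No other cell type list passed with camera. Of 9 pericyte markers, Notch3 fell over all genes; adjusted over the list alone, Pdgfrb and Abcc9 rose, and Notch3, Ndufa4l2 (-0.58) and the proteoglycan gene Cspg4 (-0.42) fell (camera adjusted p = 0.588). Among 12 arterial identity markers, 0 passed in limma over all genes or adjusted over the list alone and 2 had an unadjusted p under 0.05, with values of -0.51 for the connexin gene Gja4, 0.20 for Nrp1 and 0.19 for Sox17 (camera adjusted p = 0.900). Of 6 venous identity markers, Nrp2 (0.44) rose adjusted over the list alone and passed over all genes on another probe set (0.81, adjusted p = 0.0348), beside values of -0.23 for Nr2f2, 0.12 for Flt4 and 0.20 for Emcn (camera adjusted p = 0.509). Of 10 Schwann cell and nerve markers, Gfra3 (-0.33) fell adjusted over the list alone, beside values of -0.22 for Ncam1 and -0.18 for Sox10 (camera adjusted p = 0.0752, and 0.00886 without Notch3+/+ replicate 3). Of 7 keratinocyte markers, Perp fell over all genes, and adjusted over the list alone Krtdap (0.60) rose as well; Krt5 read 0.20 and Lor 0.16 (camera adjusted p = 0.928). Of 5 tendon markers, Thbs4 (0.77) rose adjusted over the list alone, beside 0.41 for Fmod (camera adjusted p = 0.212). The 3 cartilage markers, Col2a1 (0.17), Col9a1 (-0.08) and Acan (-0.06), did not pass, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.807). Of the 2 erythroid markers tested, Hbb-b2 read 0.77 and Alas2 0.43. Hbb-b2 passed adjusted over these 2 alone but not over all genes (adjusted p = 0.24 in limma), and its other probe set read 0.16. The signs of median, mean and test did not all match for the keratinocyte, arterial identity, cartilage and integrin lists.

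Among cellular programmes, immediate early and stress genes were higher and oxidative phosphorylation genes lower. Of 23 immediate early and stress genes, 19 were positive, with a median of 0.26 (camera adjusted p = 0.00397, and adjusted p = 0.757 with an estimated correlation). The heat shock protein genes Hspa1b (0.63) and Hspa1a (0.46) rose adjusted over the list alone, Klf4 (0.54) and Klf6 (0.29) did not pass, and 0 passed in limma over all genes, against 5 at an unadjusted p under 0.05. Hspa1a and Hspa1b lie within 20 Mb of Notch3 on its chromosome. The list was not called without Notch3+/+ replicate 2 (adjusted p = 0.101). Its medians per pool overlapped, at 0.31 in Notch3+/+ replicate 1 against 0.16 to 0.33 in the Notch3-/- pools. Of 19 oxidative phosphorylation genes, 17 were negative, with a median of -0.09 (camera adjusted p = 0.020, and adjusted p = 0.757 with an estimated correlation). In limma 0 passed over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. Atp5a1 read -0.27, Atp5b -0.18, Uqcrc1 -0.36 and Cox5a 0.36. That call was lost without Notch3-/- replicate 1 (0.324) or Notch3+/+ replicate 3 (0.0604). The oxidative phosphorylation medians per pool overlapped, at -0.060 to 0.043 in Notch3+/+ and -0.153 to -0.057 in Notch3-/- pools. None of 20 cell cycle, 15 circadian clock or 9 interferon-stimulated genes passed in limma over all genes or adjusted over the list alone, and 0, 0 and 1 had an unadjusted p under 0.05, with camera adjusted p of 0.896, 0.454 and 0.163. Members read -0.25 for Aurka and 0.25 for Kif20a, 0.66 for Npas2 and -0.48 for Per3, and -0.31 for Bst2 and -0.37 for Ifit3. Without Notch3-/- replicate 1 the cell cycle median was -0.31 (adjusted p = 0.00142) and without Notch3-/- replicate 3 it was 0.21 (0.0232). The interferon list passed without Notch3+/+ replicate 1 (0.0152) or Notch3-/- replicate 1 (0.0276).

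Of the 27 lists, 10 passed with camera, 5 higher and 5 lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.757. The ion channel, mast cell, leukocyte and fibroblast lists, 4 of the 10, were called whichever array was left out. Yet the ion channel, mast cell and leukocyte medians per pool overlapped between genotypes. The fibroblast medians did not, at -0.11 to 0.04 in Notch3+/+ and 0.10 to 0.26 in Notch3-/- pools. Fry, which tests whether the members of a list move one way without comparing them with other genes, called 2 lists, the pericyte (adjusted p = 0.00707) and keratinocyte (0.024) lists, in which Notch3 and Perp are members. For change in either direction, fry called 13.

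On the chromosome of Notch3, Rcan2, Clic5 and Guca1a were the genes called by their brightest probe set within 20 Mb, leaving Notch3 itself out. They made 3 of 445 genes tested there, or 0.674% (95% exact Clopper-Pearson interval 0.139% to 1.96%), against 37 of 12235 elsewhere, or 0.302%. An excess near Notch3 was not shown by a one-sided Fisher's exact test (p = 0.165), and with 3 called genes there it is not excluded. Without Notch3+/+ replicate 1 or Notch3-/- replicate 2, Guca1a was no longer called and the share was 0.449%. Without Notch3+/+ replicate 2, Notch3+/+ replicate 3, Notch3-/- replicate 1 or Notch3-/- replicate 3, Rcan2 alone was called and the share was 0.225%, which without Notch3-/- replicate 1 lay below the 0.278% elsewhere. Within 5 Mb, 0 of 202 genes were called (Fisher's exact p = 1). With any probe set of a gene counted, a setting chosen after seeing the data, Gtpbp2 joined the called genes within 20 Mb. The share was then 0.899% against 0.384% elsewhere (one-sided Fisher's exact p = 0.103).

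No sex-linked transcript passed between the genotypes, and 0 of 4 had an unadjusted p under 0.05 in limma. Xist, transcribed from the inactive X chromosome, read 9.75 ± 0.29 (SD, n = 3) in Notch3+/+ and 9.46 ± 0.28 (SD, n = 3) in Notch3-/- pools, and the Y-linked Eif2s3y read 7.31 ± 0.25 and 7.51 ± 0.27 (SD, n = 3). The adjusted p from limma was 0.584 for Xist and 0.671 for Eif2s3y. Kdm5d changed by 0.29 and Uty by -0.16, and neither passed.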

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

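The splits below were planned before their results were seen. The dim probe sets were examined as data that the comparisons leave out. Of the 10 ways to divide the 6 arrays into 3 and 3, 1, the real one, gave 68 probe sets past the threshold, and the highest count among the others was 0. For the gene lists the real division gave 10 lists, as only 1 of the 10 divisions did, and the highest count among the others was 8. With 10 divisions a share under 0.05 cannot be reached.

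Among the probe sets left out of the tests as too dim, AI662270, an unnamed transcript, differed between the genotypes. It read 3.06 ± 0.16 (SD, n = 3) in Notch3+/+ and 3.94 ± 0.08 (SD, n = 3) in Notch3-/- arteries, higher by 0.87 in log2 units, with an adjusted p of 0.0259 in limma without the level filter. A second dim probe set of Drd1 was lower in the same fit, by -1.11 (adjusted p = 0.00499), in the direction of its brighter probe set. Of the 64 chip controls, 0 passed in limma, 8 had an unadjusted p under 0.05 and the largest change was 0.77.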

How the results depend on the processing

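All 41 called genes kept their direction in every setting run. Their pools did not overlap between genotypes, so omitting or weighting arrays could not have reversed it. Called probe sets numbered 978 with array weights (606 higher, 372 lower), 106 with the array-name number as a random block (57 and 49) and 142 at an adjusted p under 0.10 (80 and 62). Leaving out 1 array gave 13 to 62 (6 to 37 higher, 7 to 28 lower). Without the level filter there were 59. Notch3 stayed called at changes of -3.96 to -3.52. Of 27 gene lists, 6 passed with the mean of all probe sets per gene, 0 with an estimated correlation, 2 with directional fry and 7 to 9 without 1 array. The skeletal muscle median was 0.11 with array weights (adjusted p = 0.897, against 3.76e-10 to 0.757 in the other settings), and the cell cycle median ran from -0.31 to 0.21 without 1 array. Apart from those with fewer arrays, the causes were not tested. Across settings, values of named genes stayed on their side of the threshold in 1911 cases, lost the call in 112 and gained it in 42. Lost calls can come only from genes called in the main fit, a minority of those named. Reversals, counted only where a value was called, numbered 0. Uncalled values of named genes and gene lists changed sign in 38 cases, which count as staying. The share of called genes near Notch3 had p from 0.0951 to 1, including any probe set per gene (0.103), which was chosen after seeing the data. The labels do not state whether the title numbers pair the pools. Same-numbered pools' deviations correlated at 0.24, 0.05 and -0.07, and only the pools numbered 1 correlated best with each other. These correlations rest on too few pools to decide on a pairing. With the title number as a replicate block 57 probe sets were called, 45 of the 68 among them. The file has no detection calls, so signal over background is unknown; 5 called probe sets had a group mean under the level filter.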

Other observations

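Further genes passed through a probe set other than their brightest, and these, like the pairing of genes below, were chosen after their values were seen. S1pr3, a sphingosine 1-phosphate receptor gene, fell by 1.18 (SE 0.16, n = 3 per genotype, adjusted p = 0.0418 in limma), and its brightest probe set read -0.88. Nrip2 fell by 1.10 and 1.22 on 2 probe sets. Ankrd1 rose by 1.88, the receptor phosphatase gene Ptprz1 by 1.69, the complement gene C1qb by 1.07, the neuropilin gene Nrp2 by 0.81, the carboxypeptidase gene Cpm by 0.78, Rad21 by 0.75, Ptgfr by 0.73 and Tm6sf1 by 0.60. Gtpbp2, which lies within 20 Mb of Notch3, fell by 0.95 on 1 probe set, while its brightest read -0.20. Rad21 also had a probe set that read -0.10. Together they make 11 genes beyond the 41.

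Some called genes lay outside the 15 largest changes in each direction. Nt5e, the ectoenzyme that forms adenosine from AMP, rose by 0.85 (SE 0.09), from 6.17 ± 0.07 to 7.02 ± 0.13 (SD, n = 3), beside the rise of 1.09 in Ada, which degrades adenosine. Pde1a, a calmodulin-dependent phosphodiesterase gene, fell by 0.75. The hyaluronan receptor gene Cd44 rose by 0.61 and Dner, a Notch-related transmembrane protein gene, by 0.76. Glipr1 (0.85), Pamr1 (0.87), Fhdc1 (0.84), Proser2 (0.73) and Ism1 (0.71, with probe sets from 0.24 to 1.30) also rose. All of these were lost in at least 1 omission of an array. Without Notch3+/+ replicate 2 the adjusted p was 0.127 for Nt5e, 0.31 for Pde1a, 0.329 for Cd44 and 0.244 for Dner.

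For the patterns that follow, the test of flanking sequence was planned before its result was seen, and the other tests were chosen after. Rcan2, Clic5 and Guca1a were called within 20 Mb of Notch3, where a targeted allele may carry sequence of another strain; with 1 array left out, Rcan2 stayed called in 6 of 6 cases, Clic5 in 2 and Guca1a in 0. A strain variant under 1 probe set alone is argued against for Rcan2 and Clic5. Beside the probe sets that represent them, Rcan2 fell by 2.34, and Clic5 rose by 1.01 and 0.81, each by more than 2 standard errors. The change of 0.81 did not pass (adjusted p = 0.37 in limma). Variants under several probe sets were not tested. Real expression differences carried by flanking sequence stay open: called genes were not shown to be more frequent near Notch3 (one-sided Fisher's exact p = 0.165), and the interval of the share there, up to 1.96%, also includes an excess. Guca1a had 1 tested probe set, so a variant under it stays open too. For Gtpbp2, which lies in the same window, 1 probe set fell by 0.95 while its brightest read -0.20. A variant under 1 probe set stays open there as well. Hspa1a and Hspa1b, not called over all genes, also lie in the window, and strain sequence was not tested for them. The loss of Notch3 as the reason for these changes was not tested.

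Mast cell and leukocyte markers were higher in Notch3-/- pools, with medians of 0.76 and 0.41. A lower share of smooth muscle cells would raise markers of other cell types alike. The endothelial markers did not rise as a group, with a median of -0.0867 (SD of members 0.201) and the highest of 16 members at 0.20. The mast cell minus endothelial median was higher in Notch3-/- pools by 0.86 (SE 0.376, exact two-sided permutation p = 0.1). Its lowest Notch3-/- pool, at 0.662, barely exceeded the highest Notch3+/+ pool, at 0.66. The leukocyte minus endothelial gap of 0.51 (SE 0.275, exact two-sided permutation p = 0.2) was under 2 SE. With 3 pools a side, neither gap decides on a lower share of smooth muscle cells. Pool-to-pool variation in mast cells or leukocytes stays open, since the highest Notch3+/+ pool exceeded the lowest Notch3-/- pool in both (0.65 against 0.52, and 0.30 against 0.14) and the exact two-sided permutation p was 0.2 for each, where 0.1 is the smallest that 3 against 3 allows. A genotype effect on mast cells or leukocytes cannot be told apart from this variation with 3 pools a side.

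Des and Casq2, higher, and Pgam2 and Pln, lower, were picked from the called genes after their values were seen, as genes best known from striated muscle. Des, Casq2 and Pln belong to the fixed contractile list, and 0 of the 17 skeletal muscle markers passed over all genes in limma. The falls were not called without Notch3+/+ replicate 2 (adjusted p = 0.244 and 0.128). Skeletal muscle carried over with the tail artery is argued against for the rises, as far as the fixed list marks it. The skeletal muscle median was -0.27, and from -0.71 to 0.33 in the Notch3-/- pools, against rises of 2.01 and 1.62. Such carry-over as the whole of the falls is argued against as well. The lowest of the 17 markers read -0.63, against changes of -1.02 for Pgam2 and -2.05 for Pln. In Notch3-/- replicate 3, where the skeletal median was 0.33, Pgam2 (6.19) and Pln (4.91) still read below every Notch3+/+ pool (lowest 7.05 and 6.91). Striated muscle marked by other genes was not tested. An effect of the genotype on Des, Casq2, Pgam2 and Pln within the artery stays open as a hypothesis, found and tested on the same 6 arrays. Cross-reaction of probes, which the suffix of the Casq2 probe set allows for, was not tested.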
